A study of Mus musculus with 6 samples.

How the data were processed

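Ribosome-protected fragments (footprints) were measured in the mouse pancreatic acinar cell line 266-6, in 3 libraries of wild-type (WT) cells and 3 of Mettl18 knockout (KO) cells. Per the labels' protocols, both genotypes carried a plasmid for FLAG-tagged Reg1 and were cultured for 48 h. They were lysed with 100 μg/ml cycloheximide, a drug that holds ribosomes on the mRNA, and the lysates were digested with RNase I. Ribosomes were pelleted, fragments were size-selected and ligated to a linker, and ribosomal RNA was depleted. Per the submitters' processing notes, CASAVA 1.8, cutadapt 3.7, UMI-tools 1.1.2, STAR 2.7.0a and the genome build mm10 were used; their roles, and the counting program, annotation release, strand setting and fragment lengths kept, are not given in the sources used here. No matched RNA-seq was used here, so footprint abundance was compared, not translational efficiency.

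The authors deposited raw counts of footprints, 1 file per library, with 142314 rows that each hold an Ensembl transcript identifier, a length value and a count. The deposited length value was the same in all 6 files and ran from -9 to 35381 over 67139 rows. Its unit is not stated, and values below 0 show that it is not a plain length. It is treated here as a length of the coding region less an unstated constant, which is an assumption. Its remainders on division by 3 were nearly even (33.2%, 33.2% and 33.6%), which argues only against a length in nucleotides of whole codons. All lengths below are this value, not the coding length, and "long" and "short" refer to it; an added constant would not change the order of transcripts. The other 75175 rows had no length value and a count of 0 in every library. Isoforms have rows of their own and shared footprints appear in each of them, so totals over rows count some footprints more than once. Those totals ran from 4395120 to 8227023.

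The files do not pair the identifiers with gene names, and the reference table used here (GRCm38.p6) lists no Ensembl identifiers, so it matched 0 of the 142314 by construction. Mettl18, Rpl3, Reg1 and the gene lists fixed before the data were examined (digestive enzymes, stress responses, chaperones, ribosomal proteins, markers of other cell types and others) were therefore not analysed here. The relation of footprint change to tyrosine codon content needs coding sequences, and codon occupancy needs footprint positions, so neither was analysed here. Coordinates are not given for the same reason.

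Of 54710 rows with a count in any library, rows with identical counts in all 6 libraries were kept once, which left 39355 distinct rows. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with filterByExpr and TMM scaling, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. It ran on 30588 rows, called transcripts below although several can belong to 1 gene. Log2 fold changes are KO over WT, and their standard errors were derived from the fold change and the F statistic. These standard errors are approximate, and for large changes on few counts they can lie below the counting error. Levels are TMM-scaled CPM (counts relative to the library total). The planned rule for named genes required an adjusted p under 0.05, WT and KO libraries that do not overlap and a mean of at least 5 CPM. With identifiers only, the 2 transcripts with the largest rise and the 2 with the largest fall are named, 1 per family of rows that share reads, and the exceptions for predicted genes, pseudogenes and histones were not applied. A family links rows within 10 lines of each other whose counts lie within 2-fold in every library; this rule, the classes of length value and level, and the long-against-short contrast were chosen after seeing the data. That contrast is, per library, the median log2 deviation from the 6-library mean of transcripts with a length value of at least 1000, minus that of transcripts with one under 200. It used transcripts of at least 5 CPM and an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Alternatives covered scaling, filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), glmTreat, a replicate block, leaving out each library, equal totals and removal of the length trend.

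On simulated counts for this comparison (30588 rows, 200 of them changed, 50 per fold size), the test recovered 0 of 50 changes of 1.5-fold, 16 of 50 of 2-fold, 45 of 50 of 4-fold and 50 of 50 of 8-fold. It made 120 calls, 9 of them false. With so few changed rows, the Benjamini-Hochberg cut-off was stricter than in the data, where 9.43% of rows were called. The simulated libraries were also independent, without a length trend or a close pair, so these rates do not carry over to the real comparison. A simulated length contrast of 0.5 log2 in 1 library was recovered as 0.50. The labels do not say that the libraries of a genotype came from separate cultures or clones, so p-values measure the spread between these libraries, which may be technical. Shared replicate numbers showed no consistent pairing of the libraries: deviations from the group means correlated at -0.04 for number 1, 0.40 for number 2 and -0.38 for number 3. These deviations also carry the length trend, so a shared day or batch by number is not excluded.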

Results

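The study asked how loss of METTL18, a methyltransferase that modifies a histidine of the ribosomal protein RPL3, changes translation in pancreatic acinar cells. Ribosome footprints were counted per transcript in 3 WT and 3 Mettl18 KO libraries of 266-6, a mouse cell line that keeps features of the enzyme-secreting acinar cell. After rows with identical counts were merged, the WT libraries held 4240543, 3792964 and 5131937 counts and the KO libraries 7022164, 7106203 and 5379044. The KO libraries were thus the deeper ones. The 100 highest transcripts took 11.5% ± 1.82 of the counts in WT and 13.4% ± 1.14 in KO (SD, n = 3 each), a difference of 1.97 percentage points that the test did not distinguish from chance (exact two-sided permutation p = 0.2).

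The transcript of Mettl18 itself was not analysed here, because the identifiers are not paired with gene symbols, so the genotype labels were not checked against the targeted gene. Libraries of the same genotype correlated at 0.916 to 0.985 (Pearson's r of log2 CPM across transcripts, which are not independent), and libraries of different genotype at 0.888 to 0.938. The first principal component held 49.0% of the variance and placed all 3 KO libraries on one side (19.3, 59.1 and 58.5) and all 3 WT libraries on the other (-40.2, -18.8 and -77.9). Within each genotype, the order of libraries on it was that of the long-against-short contrast given below, so its 49.0% does not measure genotype alone. KO replicates 2 and 3 were the closest pair. Their chi-square per degree of freedom was 1.35, against 4.95 to 12.2 within WT and 5.38 to 5.77 between either of them and KO replicate 1. A ratio above 1 shows a difference beyond counting noise, not that the libraries came from separate cultures. They were kept as separate samples; summed as 1 sample, they left 436 risen and 356 fallen transcripts in place of 1571 and 1314.

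Footprints rose on 1571 transcripts and fell on 1314 in Mettl18 KO cells, together 9.43% of the 30588 tested. The median change among these was 2.02-fold upwards and 2.10-fold downwards. At least 2-fold changes made up 810 of the rises and 731 of the falls. Changes of at least 4-fold were seen for 96 risen and 173 fallen transcripts, and changes of at least 8-fold for 33 and 62. The risen transcripts held 5.35% ± 0.315 of the tested counts in WT and 10.3% ± 0.414 in KO, and the fallen ones 5.49% ± 0.0239 in WT and 2.56% ± 0.151 in KO (SD, n = 3); these transcripts were selected on the same libraries. WT and KO levels did not overlap for 30.8% of tested transcripts. The share by chance is 10% only on average over splits of independent libraries. KO replicates 2 and 3 may not be independent, and transcripts share reads and trends, so the excess over 10% is not a measure of genotype alone. The calls are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The number of calls was lowest where the close KO replicates 2 and 3 were not both separate samples. It was 368 risen and 302 fallen without KO replicate 2, 410 and 312 without KO replicate 3, and 436 and 356 with the pair summed. Without KO replicate 1, which kept the pair, it was 1154 and 867, and without WT replicate 1 it was 714 and 689. If KO replicates 2 and 3 are not independent samples, 1571 and 1314 may be too high. Falls outnumbered rises without WT replicate 3, at 1431 against 1345, and with library sizes alone in place of TMM scaling, at 1762 against 1409. With 1 row per family of rows that share reads, 686 of 14155 rose and 612 fell.

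**Figure D1:**
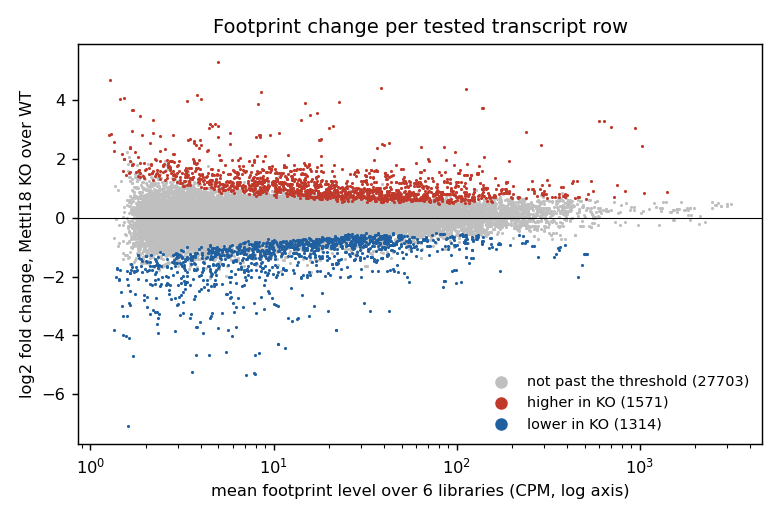
Each point is 1 of 30588 tested transcripts, with its mean level over the 6 libraries (CPM, log axis) against its log2 fold change, KO over WT. The 1571 transcripts that rose are red and the 1314 that fell are blue; among the 100 highest, 11 rose and 0 fell.

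Among transcripts of at least 5 CPM whose groups did not overlap, 1 per family, the largest rise was that of ENSMUST00000219730.1, with a length value of 191. It went from 3.41 ± 0.237 CPM in WT to 74.1 ± 1.27 CPM in KO (SD, n = 3), a log2 fold change of 4.44 ± 0.18 (SE; edgeR adjusted p = 9.71e-06), on 13 to 19 counts per WT library and 382 to 521 per KO library. ENSMUST00000067085.6, with a length value of 503, rose from 10.5 ± 2.47 to 215.5 ± 17.0 CPM, a log2 fold change of 4.37 ± 0.20 (SE; edgeR adjusted p = 2.36e-05). Its rise was the larger without WT replicate 2 (log2 4.58 against 4.48), without KO replicate 1 (4.436 against 4.432) and at equal totals (4.27 against 4.24). In the other alternatives it was the smaller, so the order of these rises is not settled. The largest fall was that of ENSMUST00000028465.13, with a length value of 388, which stands for 3 rows that share reads. It went from 15.4 ± 3.72 to 0.354 ± 0.192 CPM, a log2 fold change of -5.30 ± 0.38 (SE; edgeR adjusted p = 9.73e-05). The KO libraries held 7 counts of it in all, and the ratio of WT to KO was 42.2 with a 95% counting interval of 20.1 to 106.2 (exact binomial). ENSMUST00000229619.1, with a length value of 724, fell from 15.3 ± 1.19 to 0.601 ± 0.175 CPM, a log2 fold change of -4.65 ± 0.29 (SE; edgeR adjusted p = 9.15e-05). It had 11 counts over the KO libraries, and its ratio of WT to KO was 26.2, with an interval of 14.4 to 53.3; its log2 fold change was -5.32 with the libraries thinned to equal totals. These intervals cover counting error only. Both are nevertheless wider than the SE of the same transcript implies, so those SE values are too small. The same holds for ENSMUST00000219730.1, whose ratio of WT to KO was 0.0459, with a counting interval of 0.0335 to 0.0616.

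**Figure D2:**
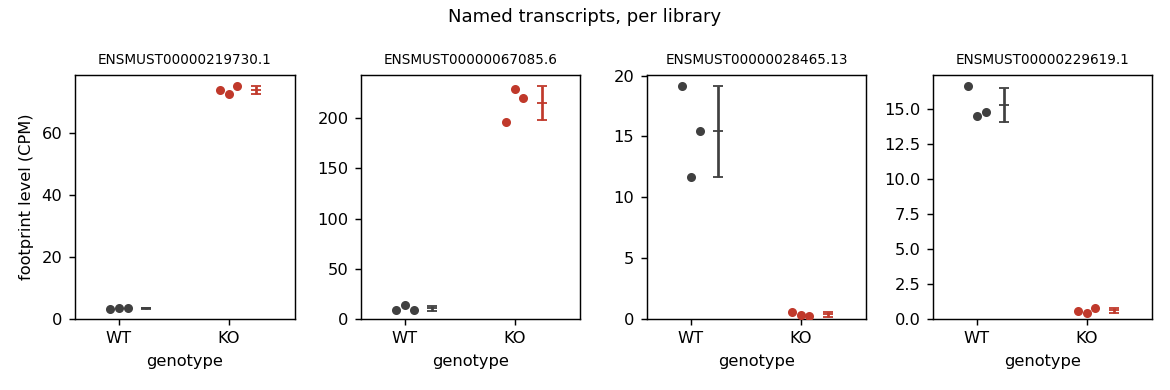
Footprint level (CPM, linear axes from 0) of the 4 named transcripts in each WT (grey) and KO (red) library; points are libraries, and bars beside them are the mean ± SD of 3. WT and KO libraries do not overlap for any of the 4.

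Among the transcripts with the most footprints, rises outnumbered falls, as counted over transcripts, which are not replicates. Across libraries, the share of counts on each library's own 100 highest rows overlapped between genotypes. It was 13.5% in WT replicate 2 and 12.1% in KO replicate 1 (exact two-sided permutation p = 0.2 for the genotypes). Within WT this share was lowest in replicate 3 (9.89%), which had the highest long-against-short contrast given below, and highest in replicate 2, which had the lowest. In KO, replicate 1 had the lowest share and the highest contrast. The level classes were not recomputed with the length trend removed, so their changes are not told apart from it. Of 1877 transcripts at 100 CPM or more, 190 rose and 81 fell, and the median log2 fold change was 0.16, against -0.06 over all tested transcripts. This class kept a positive median under each other scaling, from 0.07 with library sizes alone to 0.20 with upper-quartile scaling, and without each library in turn (0.09 to 0.27). All of these settings reuse the same libraries. In this class the counts of calls depended on which libraries were included: 62 rose and 13 fell without KO replicate 2, and 71 and 15 without KO replicate 3. They were 82 and 52 without WT replicate 1, and 404 and 77 without WT replicate 2. With library sizes alone, 227 rose and 126 fell. Of 8936 transcripts from 20 to under 100 CPM, 615 rose and 458 fell; of 12588 from 5 to under 20 CPM, 546 rose and 505 fell; and of 7187 under 5 CPM, 220 rose and 270 fell. Among the 100 highest transcripts, each of at least 557.7 CPM, 11 rose, by 0.71 to 3.30 on the log2 scale, and 0 fell in edgeR's test. The number that fell was also 0 at an unadjusted p under 0.05, in DESeq2 and in limma-voom, and the lowest of the 100 log2 fold changes was -0.24. These 100 transcripts belonged to 50 families of rows that share reads, so their number is not a number of genes.

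Transcripts in every class of the deposited length value changed in both directions. Under a value of 100, 3.50% of 3716 transcripts rose and 1.88% fell. From 100 to 199 the shares were 4.40% and 3.08% of 6679, from 200 to 399 they were 5.38% and 4.45% of 7309, and from 400 to 999 they were 5.77% and 5.39% of 9598. From 1000 to 1999 they were 6.29% and 6.00% of 2701, and at 2000 or more 5.13% and 5.81% of 585. The median log2 fold change was -0.0037 in the lowest class and -0.21 in the highest, where it was 0.14 without WT replicate 3, so its direction rested on that library.

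The libraries differed in how footprints were spread over transcripts of high and low length value, and WT and KO libraries overlapped in it. The contrast of 3050 long against 6315 short transcripts was -0.06, -0.29 and 0.47 log2 in the WT libraries and 0.17, -0.18 and -0.14 in the KO libraries. Its mean was 0.04 ± 0.39 in WT and -0.05 ± 0.19 in KO (SD, n = 3), and the difference of -0.08 lay within the spread between libraries (exact two-sided permutation p = 0.8). Without WT replicate 3 the difference was 0.13, so its sign rested on that library.

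**Figure D3:**
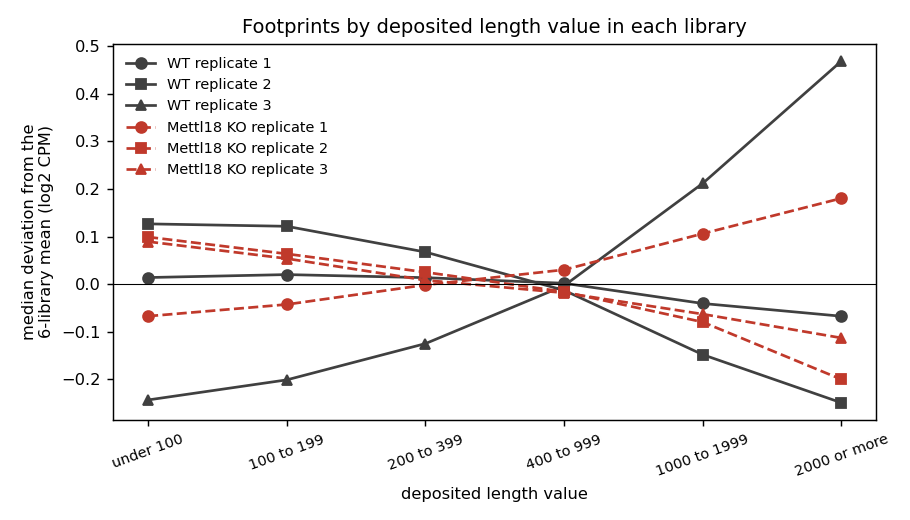
Median deviation of each library from the 6-library mean (log2 CPM) over classes of the deposited length value (unit not stated), for transcripts of at least 5 CPM; grey solid lines are WT and red dashed lines KO, with a marker per replicate. WT replicate 3 runs from -0.24 in the lowest class to 0.47 in the highest and KO replicate 1 from -0.07 to 0.18; WT replicate 2 and KO replicates 2 and 3 fall from class to class, and WT replicate 1 stays near 0 in the lower classes and ends at -0.07.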

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

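Alternatives for length and level classes, and 4 for the calls (1 row per family, length trend removed, equal totals, KO replicates 2 and 3 summed), were chosen after seeing the data. The numbers of risen and fallen transcripts were 1571 and 1314. They stayed within 1.5 times of this under DESeq2's size factors, library sizes alone, upper-quartile scaling, both other filters, DESeq2's Wald test, limma-voom, every row tested on its own, removal of the length trend and equal totals. With the replicate block they were 1168 and 944, and no call on a named transcript changed. The share of calls that were higher in KO was 54.5%, 44.4% with library sizes alone and 48.5% without WT replicate 3. The numbers were 928 and 758 when tested with glmTreat against a 1.2-fold change, 686 and 612 with 1 row per read-sharing family, and 436 and 356 with KO replicates 2 and 3 summed as 1 sample. Leaving out each library gave 368 to 2223 risen and 302 to 1718 fallen transcripts. The lowest values were those without KO replicate 2, and 660 of the 670 calls made then were also made with all libraries, in the same direction; the highest were those without WT replicate 2. Each of the 4 named transcripts kept its direction and an adjusted p under 0.05 in all 20 alternatives, with adjusted p up to 0.0021. They were picked as the largest changes in the same libraries, so this is not independent support. The log2 fold change ran from 4.24 to 4.48 for ENSMUST00000219730.1, from 4.27 to 4.58 for ENSMUST00000067085.6, from -5.81 to -5.08 for ENSMUST00000028465.13 and from -5.32 to -4.47 for ENSMUST00000229619.1. The difference in the long-against-short contrast was -0.08, and -0.25 to 0.13 with each library left out, and the median change at a length value of 2000 or more was -0.21, and -0.36 to 0.14; both were positive only without WT replicate 3, and the cause was not tested. Simulated 1.5-fold changes were not recovered, but with 200 of 30588 rows changed the cut-off was stricter there than in the data. How many small changes the real test missed is thus not known, and transcripts without a call are not shown to be unchanged. Gene list tests, the tyrosine codon relation, codon occupancy, sums of rows per gene and library sizes without Reg1, Mettl18 and mitochondrial genes were not run.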

Other observations

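The tests here were chosen after the result was seen, except that the bounds for the range without the 100 highest transcripts were set before that range was computed. For the calls between genotypes, 10 splits of the 6 libraries into 3 and 3 exist, and 1 of them, the real one, gave 2885 calls; the highest of the others gave 0 by edgeR's adjusted p. At an unadjusted p under 0.05 the real split gave 7950 transcripts and the highest other gave 5230; that one set WT replicates 1 and 3 and KO replicate 1 against the rest. With 10 splits the share cannot fall under 0.05. The other splits also place WT and KO libraries in the same group. Any difference between them, whatever its cause, then adds to the spread within groups and lowers the calls. The 0 is thus no separate evidence for an effect of genotype. At equal totals, 72.9% of the calls remained with the same direction, so these did not need the greater number of counts in the KO libraries. Thinning keeps each library's proportions, so most calls could be expected to remain whatever their cause. A property tied to depth that changes proportions is not covered, and depth as a cause is left undecided. The difference in length trend between libraries as the whole cause is argued against by its size. The long-against-short contrast differed by -0.08 log2 between group means, while the median log2 fold changes of the calls were 1.02 and -1.07. With each library's length trend removed, 93.3% of the calls remained with the same direction, which adds little, because removing so small a group difference could hardly undo them. A difference between the cell populations that is not due to Mettl18, such as separate clones or cultures, stays open, since the labels do not say how the libraries of a genotype are related. Summing the close KO replicates 2 and 3 as 1 sample left 792 calls, 774 of them shared with the 2885, with fewer samples in the test; the log2 fold changes of the 4 named transcripts were then 4.44, 4.35, -5.28 and -4.66, against 4.44, 4.37, -5.30 and -4.65, so this does not tell such a difference from an effect of the knockout.

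The spread of footprints over transcripts of high and low length value differed most within WT, where the contrast ran from -0.29 to 0.47 log2. At equal totals the range over the 6 libraries was 99.6% of the range as deposited. Depth as the cause is left undecided by this, because thinning keeps each library's proportions and medians over so many transcripts can hardly move. A few transcripts taking most of the counts are argued against by their shares: the 100 highest took 9.89% to 14.3% of the counts of a library, and the highest 0.223% to 0.391%. The range without the 100 highest, 99.6% of that with them, decides nothing, because medians over 3050 and 6315 transcripts can hardly move when so few are left out. Mettl18 genotype as the whole cause is argued against by a difference between group means that was 11.1% of the range within WT. WT replicate 3 and KO replicate 1 lay on the same side. Their deviations from the group means correlated at 0.62 across transcripts, the highest value between genotypes. WT replicate 2 gave 0.40 with KO replicate 2 and 0.38 with KO replicate 3. These deviations include the length trend itself, so their correlations are not separate evidence on its cause. A shared step of handling or library preparation, such as digestion or fragment recovery, may be involved, but no label gives one and it was not tested.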
